A study of Mus musculus with 6 samples.

How the data were processed

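RNA was taken from dense wells of AtT-20 iPAM cells, a mouse corticotrope tumour line with doxycycline-inducible PAM, and libraries were made with the AmpliSeq Library PLUS kit, which amplifies chosen stretches of transcripts, and run together in 1 lane, per the labels' protocols. There are 3 basal and 3 induced libraries; induced cells received doxycycline at 4 micrograms per ml for 48 h, and none of the basal libraries did. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Doxycycline and raised PAM go together in this design.

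Per the submitters' processing notes, the authors used Bowtie2 2.1.0.0, TopHat2 2.0.9, Cufflinks 2.2.0, Cuffdiff 2.2.0, DESeq2 and limma with the genome build mm10. The authors' settings, the gene annotation and the versions of their DESeq2 and limma are not given in the sources used here. The main sheet is named for FPKM, but each of its 6 library columns sums to 1000000, so the deposited values are TPM, that is, FPKM rescaled to a fixed total. They keep no depth, and the labels' 16.6 M reads per library is a stated figure that the values cannot test. In amplicon libraries reads do not scale with transcript length, so levels are compared within a gene across libraries and not between genes. The deposited main sheet also holds a ratio column and a log2 column. The ratio column was used to find the scale the authors applied to each library. Per the file headers, the authors' deposited table from Cuffdiff gives FPKM per group, a log2 fold change and a q-value. The authors' deposited table from DESeq2 gives a mean FPKM, a log2 fold change and an adjusted p-value, per the file headers. The authors' deposited table from limma gives a log2 fold change with its interval, a test statistic, p-values and a B score, per the file headers. The deposited core list gives symbols alone. The column names give the group and a number from 1 to 3, whereas the labels identify libraries by letters, so columns were matched to groups only. The sheet holds 23349 genes, 6551 of them at 0 in all libraries. In it 27 gene names had been turned into date numbers by spreadsheet software; they were kept in the fit and are not named.

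The test was fixed before the data were examined for values called FPKM; the values proved to be TPM, and the same test serves both. Values were taken as log2(TPM + 1), genes with a mean of at least 1 TPM were kept (12400 genes), and groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes given as "-fold" are ratios of mean TPM, and log2 differences are from the fit, where the added 1 shrinks the change of low genes. For Pam, an exact two-sided permutation test of the 6 values was added. Gene lists were also fixed before the data were examined and tested with camera in limma at a correlation of 0.01 between genes, for the 30 lists with at least 5 tested genes, with Pam left out of every list; camera with an estimated correlation and fry were run beside it. Lists with fewer tested genes were the aquaporins (Aqp1, Aqp5 and Aqp11, 3 genes) and the markers of other pituitary cell types (3 genes), and the list of transcripts encoded in mitochondrial DNA had 0 genes in the table. Counts of members are given over all genes tested and adjusted over the list alone.

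The rule for the genes named in the text was fixed before the data were examined. It takes Pam; the 12 genes with the highest and the 12 with the lowest log2 difference among genes past the threshold whose groups do not overlap, leaving out gene models without a proper name (13 of the 148); up to 2 members of each list in each direction past the threshold, or the 2 with the smallest p; the 5 highest and 5 lowest of the core list; and genes named whatever their values, among them Aqp1, Slpi, Pomc, Pcsk1, Pcsk2, Cpe, Atp7a, Slc31a1, Cyb561, Uhmk1, Actb and Gapdh. Not every gene the rule takes is described, and a gene outside it is said to have been chosen after its value was seen; genes named for their place in the deposited tables, and Rn45s, Krt8, Krt18 and Col1a1, are of that kind.

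Alternatives fixed beforehand were pseudocounts of 0.1 and 0.01, no filter and a filter at 5 TPM, quantile normalization, rescaling by the median ratio, eBayes without a trend and with robust moderation, library weights, leaving out each library, a minimum change of 1.5-fold and thresholds of 0.1 and 0.01. A fit of raw counts, planned in case such values were found, was not run because the deposited values are TPM. Alternatives chosen after seeing the data were the column number as a block, a loess correction of each library for GC content, both together, leaving out the libraries numbered 3, the authors' scale per library, and the offset of the deposited DESeq2 table. The check behind the block was the correlation, across genes, of deviations from the group means between libraries of equal number. It was 0.461 for number 1, 0.182 for number 2 and 0.717 for number 3, all above 0.1, while 4 of the 6 libraries correlated best with their own number. Neither library numbered 2 did so. Basal 1 with induced 2 and basal 2 with induced 1 gave 0.322 and 0.284, above the value for number 2. The pairing comes from the data and the column names and not from the labels. GC content and length are those of whole transcripts in GENCODE M21 on the mm10 assembly, and not of the amplified stretches. They were matched by symbol for 21698 genes and by an older symbol for 1271, and 12281 of the genes tested (99.0%) had a value. Coordinates are from that annotation.

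The code was tested on simulated data with genes changed by known amounts, for the comparison of induced against basal libraries over 12400 genes. It recovered 100% of 67 genes changed by 2 on the log2 scale. Of genes changed by 1 and by 0.5 it recovered 62.7% and 6.06%. Of its 117 calls, 4 were unchanged genes. These rates describe the simulated data alone. In the real libraries, deviations from the group means were correlated across genes between libraries. Whether the rates hold for such data was not tested.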

Results

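The data are transcript levels from AtT-20 cells, a mouse pituitary tumour line of corticotropes, the cells that make pro-opiomelanocortin and cut it into adrenocorticotropic hormone. The line studied, called iPAM, carries a doxycycline-inducible copy of PAM, peptidylglycine alpha-amidating monooxygenase, a copper- and ascorbate-dependent enzyme of the secretory pathway that converts the glycine-extended ends of peptides into amides. There were 3 libraries from cells at the basal level of PAM and 3 from cells that had received 4 micrograms per ml of doxycycline for 48 h. The labels give 16.6 M reads per library, and the deposited values add up to 1000000 in each library, so they carry no depth of their own. Between 14491 and 15098 of the 23349 listed genes were above 0 in a library. The libraries are called basal 1 to 3 and induced 1 to 3 after the columns of the deposited table. The study's question is how gene expression in corticotropes differs when PAM is raised.

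Induction raised Pam in every induced library. The mean level went from 80.8 ± 13 TPM (SD, n = 3) in basal cells to 388 ± 125 TPM (SD, n = 3) in induced cells, a 4.8-fold difference. The basal libraries stood at 92.6, 82.8 and 66.9 TPM and the induced ones at 507, 399 and 258 TPM. In the mouse genome (mm10, GENCODE gene model ENSMUSG00000026335.16) Pam lies on the minus strand of chromosome 1, from 97795114 to 98095646. The labels do not name the species of the induced PAM sequence, so this value does not separate transcripts of the inducible copy from those of the resident gene. On the log2(TPM + 1) scale the difference was 2.21 (SE 0.26, 95% confidence interval 1.59 to 2.82; limma adjusted p = 0.0210). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 libraries against 3 can give. Without any single library other than induced 3 the limma call ended, with adjusted p between 0.0822 and 0.175, while the log2 difference stayed between 1.99 and 2.31.

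**Figure D1:**
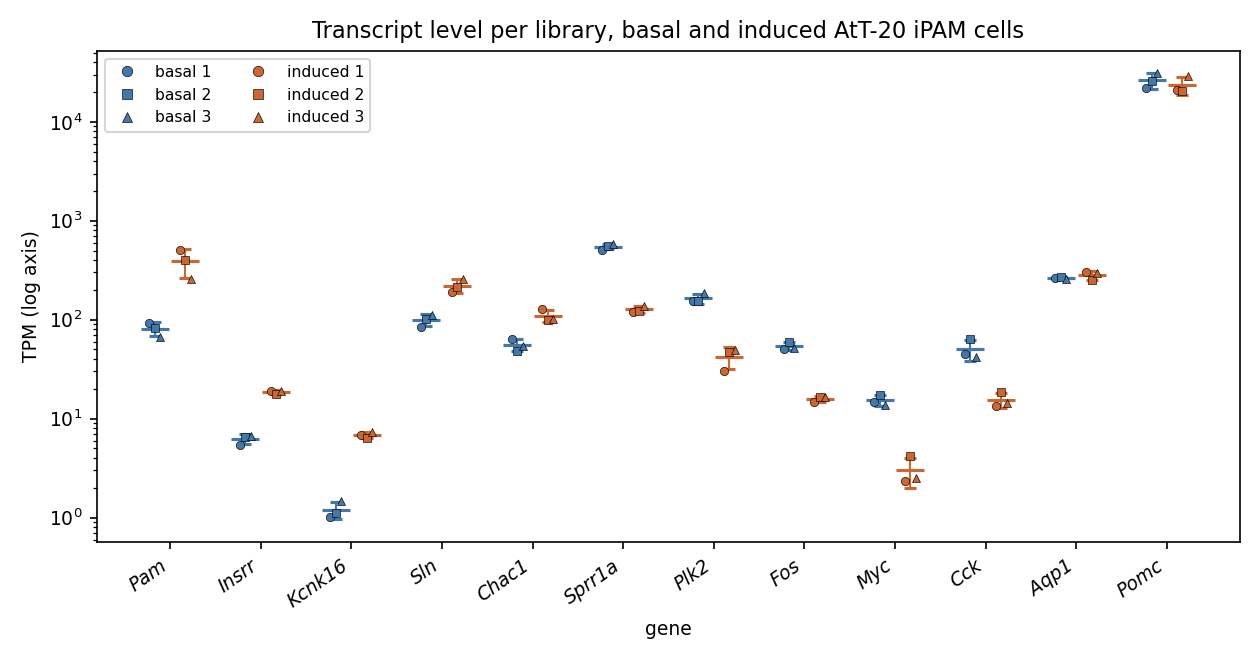
Transcript level in TPM on a log axis for named genes in each of the 6 libraries; points are libraries (circle, square and triangle for columns 1, 2 and 3), horizontal bars are group means and whiskers the SD (n = 3). Pam, Insrr, Kcnk16, Sln and Chac1 were higher in all 3 induced libraries and Sprr1a, Plk2, Fos, Myc and Cck lower, while the groups overlapped for Aqp1 and Pomc.

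Beyond Pam, the main fit called few genes higher and many more lower in induced cells. That balance changed with the setting, as given below. Of 12400 genes tested, 148 passed the limma threshold (adjusted p under 0.05), 16 of them higher and 132 lower in induced cells. Among the 12 highest were Kcnk16, a background potassium channel of the pancreatic islet, at 5.74-fold, Insrr, an alkali-sensing receptor tyrosine kinase related to the insulin receptor, at 3.0-fold, and Hpd, an enzyme of tyrosine breakdown, at 3.71-fold. Kcnk16 started near the 1 TPM level of the filter, at 1.20 ± 0.234 TPM, and reached 6.86 ± 0.540 TPM (SD, n = 3). Hpd went from 3.06 ± 0.928 to 11.4 ± 2.44 TPM (SD, n = 3). Sln, which encodes the calcium pump inhibitor sarcolipin, rose from 99.7 ± 13.7 to 221 ± 34.0 TPM (SD, n = 3), and Myot, the muscle protein myotilin, from 35.7 ± 1.23 to 75 ± 9.54 TPM (SD, n = 3). The receptors Ffar2, for short-chain fatty acids, and Cmklr1, for chemerin, rose 2.33-fold and 2.08-fold. Chac1, which degrades glutathione, rose 1.98-fold. Prrt3 rose 2.52-fold. The remaining pair, Umodl1 and Tprg, rose from 0.433 and 0.612 TPM to 2.47 and 2.2 TPM. The log2 differences of these 12 genes, Pam included, ran from 0.97 (Chac1, SE 0.16, limma adjusted p = 0.0496) to 2.21 (Pam). Kcnk16 had the smallest limma adjusted p of them, 0.0121, at a log2 difference of 1.84 (SE 0.16).

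The genes that fell most were of many kinds. Tnfrsf9, a receptor of the tumour necrosis factor family, fell from 25.6 ± 5.98 to 3.64 ± 1.35 TPM (SD, n = 3), which is 7.02-fold lower. Sprr1a, a small proline-rich protein of cornified epithelia and of injured neurons, fell from 546 ± 34.4 to 127 ± 10.6 TPM (SD, n = 3) and had the smallest limma adjusted p of all genes, 0.00705. The transcription factor Myc was 5.09-fold lower, the polo-like kinase Plk2 3.90-fold lower, and Rgcc, a regulator of the cell cycle, 4.17-fold lower. Pvrl4, a nectin, was 4.70-fold lower, the laminin chain Lamb3 3.91-fold lower and the sialyltransferase St3gal1 4.25-fold lower. Pglyrp1, a peptidoglycan-binding protein, was 4.39-fold lower, Fam71f2 5.63-fold lower and the macrophage-lysosome marker Cd68 5.35-fold lower. The histone gene Hist1h2bg was 6.05-fold lower, though reads of near-identical histone copies make single histone genes uncertain. The log2 differences of these 12 ran from -1.88 (Lamb3) to -2.54 (Tnfrsf9, SE 0.29, limma adjusted p = 0.0210).

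All 148 genes had groups that did not overlap, as did 2678 of the 12400 genes tested (21.6%, where chance gives 10%). The count depended on the model. With the column number as a block 2761 genes passed the limma threshold, 1021 higher and 1740 lower, among them all 148. The labels do not tie equal column numbers to a shared origin. The block leaves each log2 difference unchanged and alters its SE, so directions could not differ. Counts of list members with the block, given below, stand against these totals over 12400 genes. Leaving out both libraries numbered 3 gave 688 genes, 187 higher and 501 lower. Leaving out one library gave 0 genes without basal 1, without basal 2 or without induced 1, 1 without induced 2, 15 without basal 3 and 255 without induced 3 (limma), while 1130 to 1562 genes had an unadjusted p under 0.05 in the fits that called 0. The split between higher and lower also moved with the scale: quantile normalization gave 28 higher and 93 lower, and shifting the induced libraries by the offset found in the deposited DESeq2 table gave 1915 higher and 135 lower, since it moves the median of all genes to 0.36. Correcting each library for GC content gave 117 higher and 297 lower. That correction together with the block gave 1669 higher and 1747 lower. All 37 named genes past the threshold kept their sign under every other setting in which they were tested. Some of these genes lie under the filter at 5 TPM. Leaving out libraries could not reverse a sign, since the groups of these genes do not overlap. Neither could the thresholds, the variance moderation or the block, which leave the log2 difference as it is. The kept signs are therefore a weak check.

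Genes that hypoxia-inducible factor (HIF) switches on were lower as a group in induced cells. Of 29 measured members, 28 had negative log2 differences, with a median of -0.55. The peptide gene Adm fell from 120 ± 21.1 to 41.2 ± 9.15 TPM (SD, n = 3), and the circadian repressor Bhlhe40 from 247 ± 37.7 to 90.3 ± 23.7 TPM (SD, n = 3). The other 3 members that fell, named after their values were seen, were Ddit4, an inhibitor of mTOR signalling, at 2.68-fold lower, the carbonic anhydrase Car9 at 1.83-fold and Ndrg1 at 1.73-fold. Thus 5 members fell over all genes tested, 14 adjusted over the list alone and 23 with the block, and 0 rose in any of these counts. Camera in limma gave adjusted p = 7.6e-12 for the list, and adjusted p = 0.0929 with an estimated correlation. Glycolysis, which shares 8 genes with the HIF list, had a median of -0.33 over 19 genes, 17 of them negative, although that median turns to 0.10 on the scale of the deposited DESeq2 table. Gpi1, which converts glucose 6-phosphate to fructose 6-phosphate, fell from 1759 ± 49.1 to 1047 ± 45.8 TPM (SD, n = 3) and was the 1 member to pass over all genes, against 5 adjusted over the list alone and 12 with the block. The camera test in limma gave adjusted p = 6.8e-06 for glycolysis and adjusted p = 0.0727 with an estimated correlation. The glucose transporter Slc2a1, on both lists, stood at 330 ± 31.0 TPM in basal and 181 ± 38.1 TPM in induced cells (SD, n = 3; limma adjusted p = 0.0820, and 5.1e-04 with the block).

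Immediate early genes, which respond within minutes to growth signals, were lower too. Of 25 measured, 24 had negative log2 differences and the median was -0.78. Fos fell from 54.1 ± 4.77 to 15.9 ± 1.05 TPM (SD, n = 3), Atf3 was 2.79-fold lower and Btg2 2.63-fold lower, and with Myc these made 4 members that fell over all genes, 15 adjusted over the list alone and 19 with the block. Camera in limma gave adjusted p = 7.6e-12, and adjusted p = 0.114 with an estimated correlation. Targets of p53 had a median of -0.71, with 23 of 23 negative. Plk2, Btg2 and Bbc3 (a promoter of apoptosis named after its value was seen, 2.44-fold lower) were the 3 that fell over all genes, against 12 adjusted over the list alone and 16 with the block. The p53 list had a camera adjusted p of 1.9e-09 in limma, and adjusted p = 0.0727 with an estimated correlation. Genes of the S phase of the cell cycle had a median of -0.29 over 30 genes, 27 of them negative, which becomes 0.14 on the scale of the deposited DESeq2 table. E2f8, a repressor of cell cycle genes, fell from 42.8 ± 2.48 to 23.8 ± 0.574 TPM (SD, n = 3) and was the 1 S-phase gene past the threshold over all genes, against 2 adjusted over the list alone and 15 with the block. Camera in limma gave adjusted p = 1.4e-04 for S phase, and adjusted p = 0.0727 with an estimated correlation. Genes of the G2 and M phases were not past the camera threshold (median -0.08 over 32 genes, limma adjusted p = 0.246). Among them 0 passed over all genes or adjusted over the list alone, while with the block 10 fell and 1 rose.

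Mitochondrial genes of the nucleus shifted the other way, by small amounts spread over many genes. Subunits of the respiratory chain and ATP synthase had a median log2 difference of 0.20 over 78 genes, 66 of them positive, and mitochondrial ribosomal proteins a median of 0.19 over 76 genes, also with 66 positive. No member of either list passed over all genes or adjusted over the list alone (0 in each), and with the block 25 members of each rose and 2 of the respiratory list fell. Mrpl20 stood at 292 ± 14.9 TPM in basal and 470 ± 34.2 TPM in induced cells, and Mrps22 at 34.9 ± 4.15 and 54.0 ± 3.96 TPM (SD, n = 3; limma adjusted p = 0.0525 and 0.105, and 7.3e-04 and 0.00247 with the block). The respiratory genes with the smallest p went against their list: Cox6b2, a testis form of a cytochrome oxidase subunit, stood at 32.1 ± 3.29 and 12.2 ± 3.78 TPM, and Cox7a1, a muscle form, at 92.4 ± 15.1 and 47.6 ± 7.38 TPM (SD, n = 3; limma adjusted p = 0.0557 and 0.0689, and 0.00172 and 4.9e-04 with the block). Camera in limma gave adjusted p = 2.4e-08 for the respiratory list and 7.4e-09 for the mitochondrial ribosomal list, with adjusted p = 0.0727 with an estimated correlation for each.

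Genes for protein synthesis and folding also had positive medians. Cytosolic ribosomal proteins had a median of 0.11 over 80 genes, 62 of them positive, with 0 members past the threshold over all genes, 0 adjusted over the list alone and 8 with the block. With the block 1021 of all 12400 genes tested rose, so 8 of 80 is near the share over all genes. Camera in limma gave adjusted p = 0.00229 for the ribosomal list, and adjusted p = 0.422 with an estimated correlation. In limma the call also ended without basal 1, without induced 2, without induced 3 and after quantile normalization (adjusted p = 0.0534, 0.0836, 0.130 and 0.150, with medians of 0.09, 0.09, 0.07 and 0.07). Chaperones of the endoplasmic reticulum and genes of the unfolded protein response had a median of 0.16 over 32 genes, 22 of them positive, with members on both sides. Sec61b, of the translocation channel, stood at 178 ± 6.31 TPM in basal and 303 ± 35 TPM in induced cells, and P4hb, a protein disulfide isomerase, at 1411 ± 46.9 and 997 ± 69.0 TPM (SD, n = 3; limma adjusted p = 0.0515 and 0.0897, and 6.5e-04 and 0.00203 with the block). In this list 1 gene rose and 1 fell adjusted over the list alone, 10 rose and 5 fell with the block, and 0 did over all genes. Its camera adjusted p in limma was 0.0184, and adjusted p = 0.308 with an estimated correlation. Without induced 1 the limma value was 0.0659 with a median of 0.04, after quantile normalization 0.169, after GC correction 0.0950 and 0.0620 on the scale of the deposited DESeq2 table. Genes of the ATF4 stress response moved in both directions: Psph, of serine synthesis, rose from 93.6 ± 3.86 to 174 ± 19.6 TPM (SD, n = 3) and Chac1 rose as above, while Atf3 fell, and the list of 37 genes did not pass (median 0.12, camera in limma adjusted p = 0.0597).

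**Figure D2:**
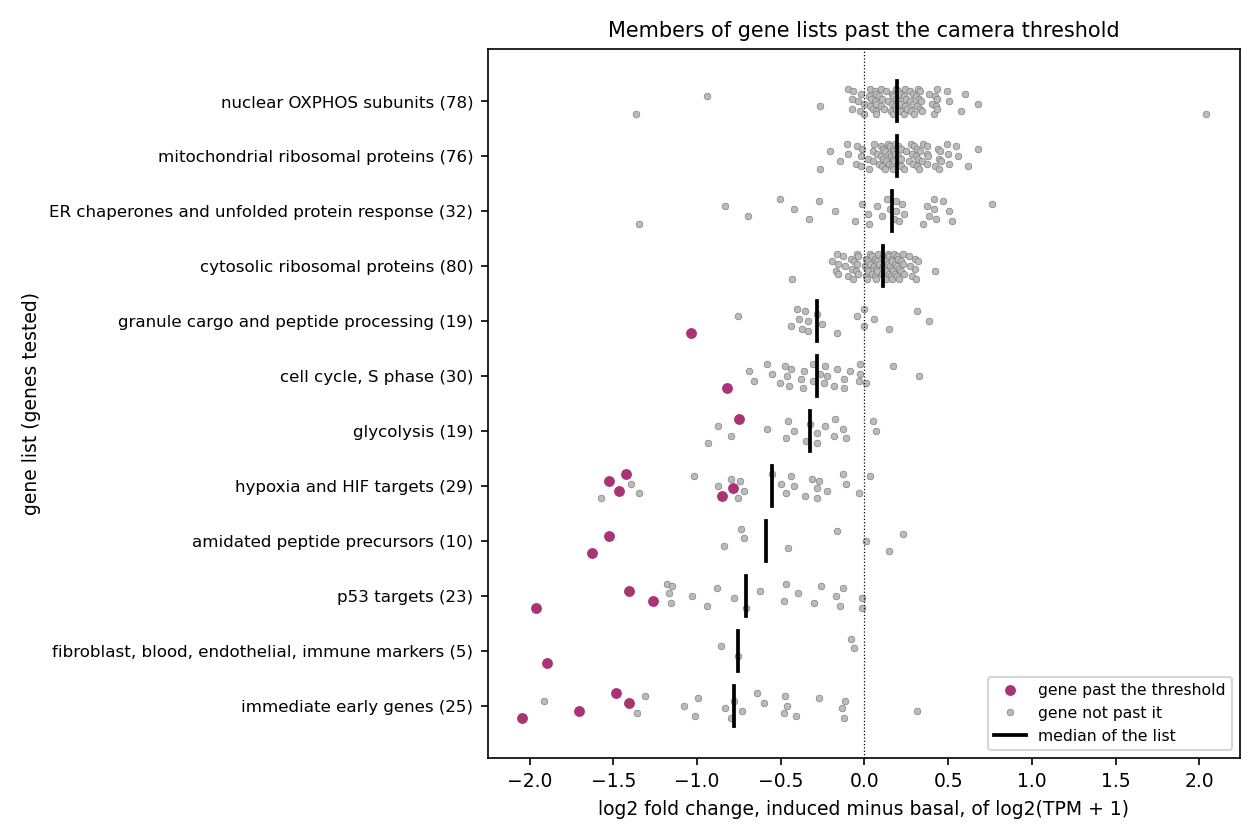
Log2 difference between induced and basal cells, on the log2(TPM + 1) scale, for each member of gene lists past the camera threshold in limma; 1 point per gene, coloured where the gene itself passed, with the median of each list as a black bar and the number of genes tested in parentheses. The 2 mitochondrial lists have medians of 0.20 and 0.19 with 0 genes past the threshold, while the HIF list and the immediate early genes have medians of -0.55 and -0.78; on the scale of the deposited DESeq2 table the medians of glycolysis, S phase and granule cargo, among the lists shown, turn positive.

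In the secretory pathway, where PAM acts, the main hormone precursor did not pass the threshold with or without the block, and the calls for Pcsk1 and Cpe depended on the block. Pomc stood at 26183 ± 4599 TPM in basal and 23484 ± 4987 TPM in induced cells (SD, n = 3; limma adjusted p = 0.791, and 0.137 with the block). The prohormone convertase Pcsk1 stood at 365 ± 72.9 and 450 ± 50 TPM, and carboxypeptidase E, Cpe, at 731 ± 192 and 540 ± 141 TPM (SD, n = 3; limma adjusted p = 0.488 and 0.536, and 0.0384 and 0.00783 with the block). The convertase Pcsk2 had means of 0.239 and 0.180 TPM, below the level tested. In the list of granule cargo and processing genes, 15 of 19 were negative with a median of -0.28, which becomes 0.12 on the scale of the deposited DESeq2 table. Pcsk6, a convertase of the constitutive pathway, fell from 1.88 ± 0.230 to 0.408 ± 0.119 TPM (SD, n = 3) and was the 1 member past the threshold over all genes, against 2 adjusted over the list alone, while with the block 7 fell and 2 rose. Camera in limma gave this list adjusted p = 0.0451, and adjusted p = 0.174 with an estimated correlation. The call in limma also ended with the block (0.0580), without basal 3 (0.230), without induced 1 (0.290), without induced 2 (0.0740), with a filter at 5 TPM (0.124), on the per-library scale of the authors (0.0576) and on the scale of the deposited DESeq2 table (0.0708). Precursors of peptides that carry a C-terminal amide, the products of PAM, had a median of -0.59 over 10 genes. Cck, the cholecystokinin precursor, fell from 50.4 ± 12.3 to 15.5 ± 2.64 TPM (SD, n = 3) and Adm fell as above, 2 members over all genes, 3 adjusted over the list alone and 5 with the block. That list's camera adjusted p in limma was 0.0115, and adjusted p = 0.174 with an estimated correlation. In limma it was 0.0773 without basal 3, 0.110 without induced 1 and 0.248 without a filter, with medians of -0.37, -0.34 and -0.16. Doc2b, a calcium sensor of exocytosis, fell from 3.52 ± 0.700 to 0.845 ± 0.295 TPM (SD, n = 3), the 1 member of the regulated exocytosis list to pass over all genes; 2 rose and 4 fell adjusted over the list alone, 4 rose and 10 fell with the block, and the list as a whole did not pass (median -0.04 over 33 genes, camera in limma adjusted p = 0.709).

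Aqp1, Slpi, Atp7a, Slc31a1, Cyb561 and Uhmk1, fixed beforehand for their known ties to PAM, did not pass the limma threshold. With the block their limma adjusted p lay between 0.0589 (Slpi) and 0.920 (Cyb561). The water channel Aqp1 stood at 263 ± 5.14 TPM in basal and 284 ± 29.5 TPM in induced cells (SD, n = 3; limma adjusted p = 0.796), and the protease inhibitor Slpi at 2.85 ± 0.919 and 1.19 ± 1.05 TPM (SD, n = 3; limma adjusted p = 0.379), with induced 3 at 0. Of the copper carriers, Atp7a stood at 6.56 ± 2.04 and 6.11 ± 2.30 TPM and Slc31a1 at 31.0 ± 6.47 and 25.7 ± 6.69 TPM (SD, n = 3; limma adjusted p = 0.937 and 0.704). Cyb561, which returns electrons to ascorbate in granules, stood at 133 ± 37.4 and 134 ± 31.5 TPM, and the kinase Uhmk1 at 23.1 ± 6.64 and 18.2 ± 6.16 TPM (SD, n = 3; limma adjusted p = 0.991 and 0.688).

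Reference genes and markers of other cell types were looked at as well. Actb stood at 1264 ± 478 and 1074 ± 689 TPM and Gapdh at 7107 ± 997 and 5183 ± 853 TPM (SD, n = 3; limma adjusted p = 0.831 and 0.247, and 0.127 and 0.00216 with the block). Of the markers of fibroblasts, blood, endothelium and immune cells, 5 were high enough to test. Cd68 fell as given above, and Col1a1 had means of 3.36 and 1.56 TPM. The keratins Krt8 and Krt18 had means of 628 and 334 TPM in basal and 615 and 192 TPM in induced cells. These keratins are genes of epithelial cells and not of the cell types the list is named for. The list therefore does not measure those cell types alone. The marker list had a median of -0.75 and a camera adjusted p of 0.0149 in limma, and adjusted p = 0.157 with an estimated correlation. In limma it was 0.0773 without basal 3 and 0.0763 without induced 1. Without a filter the median was -0.04 and the limma camera adjusted p 0.0781, so the median of -0.75 rests on the 5 genes the filter kept. Of 17 marker genes of other pituitary cell types, 3 were tested, and Ghrhr and Pax7 stood at 2.57 ± 0.355 and 2.60 ± 0.505 TPM in basal and 2.25 ± 0.792 and 2.30 ± 0.624 TPM in induced cells (SD, n = 3).

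Of the 30 lists tested, 14 passed the camera threshold in limma, 4 with higher and 10 with lower genes. With an estimated correlation 0 lists passed, although 9 had an unadjusted p under 0.05, and fry in limma called 12 lists when asked whether the genes of a list move one way. Cytosolic ribosomal proteins and chaperones of the endoplasmic reticulum passed with camera and not with fry (fry in limma, adjusted p = 0.331 for each). The lists for copper handling, iron handling, ascorbate and cytochrome b561, the proton pump, the corticotrope identity genes, oxidative stress, cholesterol synthesis, vesicle coats, endosomes and lysosomes, primary cilium, tubulins, ion channels and the interferon response did not pass, with camera adjusted p in limma between 0.124 (interferon response) and 0.898 (tubulins). Among their members, Cd63, a tetraspanin of endosomes, stood at 393 ± 2.15 and 583 ± 35.2 TPM, and Nr4a1, an orphan nuclear receptor that acts on Pomc, at 19.5 ± 1.19 and 10.9 ± 0.852 TPM (SD, n = 3; limma adjusted p = 0.0689 and 0.0585, and 0.00168 and 0.00172 with the block). Tubb3 stood at 144 ± 22.3 and 261 ± 33.2 TPM, and the haem oxygenase Hmox1 at 137 ± 13.3 and 86.4 ± 8.23 TPM (SD, n = 3; limma adjusted p = 0.0689 and 0.0810, and 8.0e-04 and 0.00117 with the block).

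The libraries numbered 3 stood apart from the rest of their groups. The first principal component of the 12400 genes held 49.0% of the variance and placed basal 3 and induced 3 at one end, and the second, with 25.9%, separated basal from induced libraries. In these libraries transcripts poor in G and C were lower than in the other libraries of the group, and those rich in them mostly higher. In the richest group of genes, at 60.4% GC, basal 3 and basal 2 had the same median deviation from the mean of all 6 libraries, 0.07. Across genes, the rank correlation of GC content with a library's deviation from the mean of all 6 libraries was 0.393 for basal 3 and 0.450 for induced 3. It was -0.482 for basal 1 and -0.369 for induced 1. Each of these values also carries the difference between the groups. Genes are not independent replicates, so no p-value is attached to these values. Actb stood at 715 TPM in basal 3 and 282 TPM in induced 3, against 1401 to 1586 TPM in the other 4 libraries. The ribosomal RNA precursor Rn45s held 1.35% of induced 2 and between 0.0857% and 0.560% of the other libraries.

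**Figure D3:**
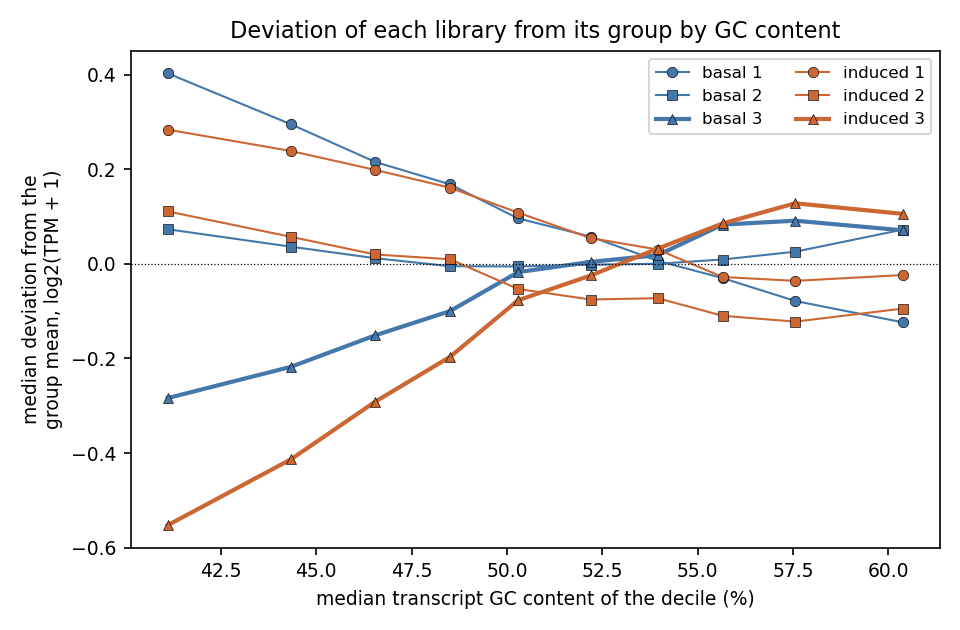
Median deviation of each library from the mean of all 6 libraries, in log2(TPM + 1), over 10 groups of genes ordered by transcript GC content. The x axis gives the median GC in percent, with 1 line per library, blue for basal and orange for induced. The y axis label and title name the group, but the values are deviations from the mean of all 6 libraries. In the lowest group, at 41.1% GC, basal 3 and induced 3 lie at -0.28 and -0.55 and basal 1 and induced 1 at 0.40 and 0.28.

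The deposited workbook also holds the authors' own calls, made on the same libraries, so their overlap with the fit described above is no independent evidence. The authors' deposited table from Cuffdiff lists 1548 genes, 559 higher and 989 lower in induced cells, the one from DESeq2 195 genes, 148 higher and 47 lower, and the one from limma 146 genes, 16 higher and 130 lower. In the deposited limma table the sign of the log2 fold change is opposite to that of the test statistic for all 146 genes, and direction is taken here from the fold change. These 3 tables share 55 genes, all with the same direction in each table and in the fit used here. The deposited core list holds 57 symbols, of which 54 are in all 3 tables. Bsg and Smox are in the authors' deposited tables from DESeq2 and limma, and Slc26a10 in none of the 3. Of the core genes, 14 were higher and 43 lower in induced cells, and 54 passed the limma threshold here. The exceptions were Dusp1, Spin2 and Slc26a10 (limma adjusted p = 0.0540, 0.0540 and 0.161), and all 57 passed with the block. Kcnk16, Hpd, Insrr, Prrt3 and Ffar2 were the highest of the core list, and Tnfrsf9, Sprr1a, Myc, Plk2 and Pglyrp1 the lowest.

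The deposited tables differ in their balance of higher and lower genes. Fold changes in the authors' deposited table from DESeq2 lay above those of the fit used here by a median of 0.43 on the log2 scale, a factor of 1.34, with a median absolute deviation of 0.0116 over the 195 genes, while those in the deposited limma table differed by a median of -0.0001. Thus Sprr1a has a log2 fold change of -1.69 in the authors' deposited table from DESeq2, -2.10 in the one from limma and -2.10 in the fit used here. Ldha, the muscle form of lactate dehydrogenase, is listed at 0.31 in the authors' deposited table from DESeq2 and had -0.11 in the fit used here, the 1 gene of that table with opposite signs.

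**Figure D4:**
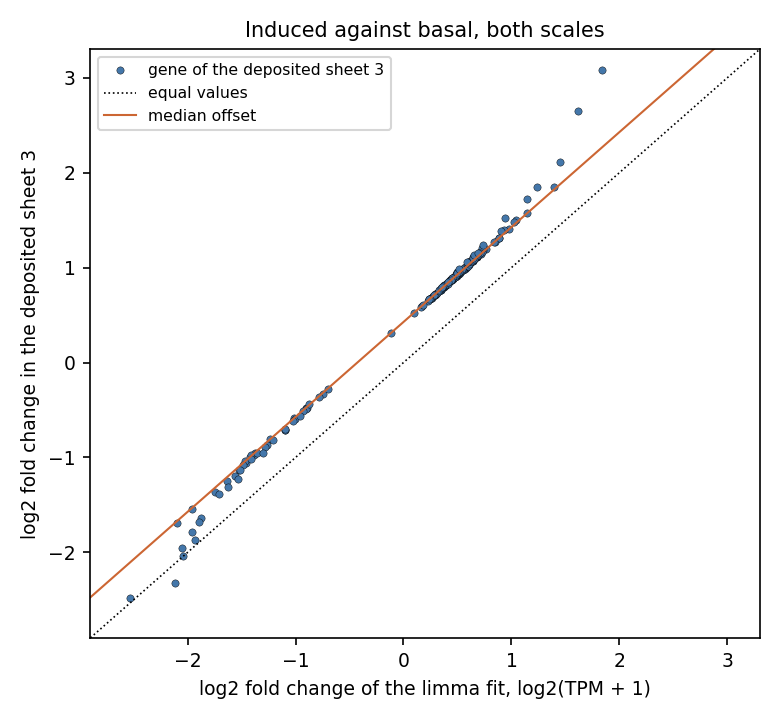
Log2 fold change of induced against basal cells for the 195 genes of the authors' deposited table from DESeq2 (y axis, labelled sheet 3) against the log2 difference of the limma fit on log2(TPM + 1) (x axis); 1 point per gene, the dotted line marks equal values and the orange line the median offset. Most points follow the line offset by 0.43.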

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

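The column block, the GC correction, leaving out the libraries numbered 3, the authors' per-library scale and the DESeq2 offset were chosen after the data were seen; the other settings were fixed beforehand. Pam passed the limma threshold of 0.05 under every scaling, filter and model with all libraries, and in the main setting it did not pass 0.01. In leave-one-out fits its log2 difference ranged from 1.99 to 2.48 and it passed only without induced replicate 3. Counts of genes changed in leave-one-out fits ranged from 0 to 255 (0 to 33 higher, 0 to 222 lower), and of lists from 9 to 14; those fits have fewer libraries. With limma, 148 genes passed in the main setting (16 higher, 132 lower), 93 with a filter at 5 TPM (8 and 85), 394 at a threshold of 0.1 (95 and 299), and 8 at 0.01 (0 and 8), out of 1871 with an unadjusted p under 0.05. Library weights gave 3500 (1341 and 2159), the column block 2761 (1021 and 1740), the GC correction 414 (117 and 297), the block and GC correction together 3416 (1669 and 1747), and leaving out both libraries numbered 3 gave 688 (187 and 501). The library weights were 4.98 for basal 2 and 4.85 for induced 2, against 0.192 to 0.681 for the other libraries. That pair thus carried most of the weight in the weighted fit. The authors' per-library scale gave 96 (14 and 82), the DESeq2 offset 2050 (1915 and 135), a pseudocount of 0.1 gave 10 higher genes and quantile normalization 28. For these the cause was not tested. Camera with an estimated correlation called 0 of 30 lists (9 at an unadjusted p under 0.05), and the settings other than leave-one-out called 12 to 15. Of the list medians that change sign under the DESeq2 offset, among them granule cargo, glycolysis and S phase, none does so relative to the median of all genes, 0.36. Lists for granule cargo, ER chaperones, cytosolic ribosomal proteins, amidated precursors and other cell types each lost their call in at least 1 setting; without a filter the last pair had adjusted p = 0.248 and 0.0781 (camera in limma). The block ended no list call but that of granule cargo. For named genes, 1833 values under other settings split into 1413 on the same side of the threshold, 246 no longer past it and 174 newly past it, with 0 reversed. Many of these settings could not reverse the sign of a gene past the threshold in the main fit.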

Other observations

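Gene groups noticed after the values were seen, and tested on the same data, add to the picture as hypotheses. The 37 subunits of the proteasome had a median log2 difference of 0.18, with 32 positive, 0 past the threshold over all genes and, with the column block, 11 higher and 1 lower; camera in limma gave adjusted p = 5.9e-06 over the 5 lists of this kind, and adjusted p = 0.0314 with an estimated correlation. Cytosolic tRNA synthetases had a median of 0.24 over 17 genes (limma camera adjusted p = 2.8e-04, and adjusted p = 0.182 with an estimated correlation), and subunits of the COP9 signalosome 0.21 over 8 genes (limma camera adjusted p = 0.00393, and adjusted p = 0.182 with an estimated correlation). Histone genes had a median of -0.72 over 27 genes, 3 of them positive (limma camera adjusted p = 2.8e-04, and adjusted p = 0.299 with an estimated correlation). Hist1h2bc, at 21.7 and 8.34 TPM, and Hist1h2bg were the 2 that passed, and reads of near-identical copies make single histone genes uncertain. The group of Etv factors and Dusp phosphatases downstream of MAP kinase had a median of -0.49 over 7 genes (limma camera adjusted p = 2.8e-04, and adjusted p = 0.182 with an estimated correlation), with Etv4 falling from 5.83 to 1.30 TPM and Etv5 from 40.0 to 13.3 TPM. The medians of these 5 lists kept their sign under quantile normalization, and the negative medians of the histone and Etv lists stayed negative (-0.41 and -0.08) under the DESeq2 offset, which raises every gene.

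Single genes outside the rule also stood out. Txnip, an inhibitor of thioredoxin that responds to glucose, fell from 638 ± 61.0 to 246 ± 21.4 TPM (SD, n = 3; limma adjusted p = 0.0135), and Bsg, a chaperone of lactate transporters, from 6348 ± 102 to 3395 ± 47.1 TPM (SD, n = 3; limma adjusted p = 0.0181). Maff fell from 96.4 to 33.2 TPM, and the circadian repressor Nr1d1 from 120 to 44.6 TPM. The hepcidin gene Hamp2 stood at 111 ± 54.4 and 408 ± 138 TPM and Dio2, which activates thyroid hormone, at 7.72 ± 1.61 and 21.5 ± 7.33 TPM (SD, n = 3; limma adjusted p = 0.0682 and 0.0769, and 2.7e-05 and 2.6e-04 with the block); reads of Hamp and Hamp2, near-identical copies, may be exchanged.

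In what follows, the tests of other splits for the main count, of GC content on the balance of calls, of transcript length and of doxycycline were chosen after the results were seen. The first pattern is the balance of 132 lower and 16 higher genes. A common shift from the per-million scaling was tested by rescaling each library to its median ratio, which left 85.8% of the calls lower, and GC-dependent recovery by correcting each library, which left 93.9% of the lower genes with a GC value (123 of 131) lower and past the threshold, although lower genes made up 71.7% of all 414 calls after it. The share of lower calls was the first GC test and fell between its bounds of 60% and 75%, and the share of lower genes kept replaced it when 138 of the 148 calls were already known to be kept. The first value argues against a common shift as the whole cause of the imbalance relative to the typical gene. Lower genes made up 63.0% of the calls with the block and 6.59% with the deposited DESeq2 offset, but neither setting corrects for GC. With block and GC correction together the share was 51.1%. GC correction alone raised lower calls from 132 to 297 and higher calls from 16 to 117, so the share fell because calls of higher genes were added. The first GC test fell between its bounds and the outcome of the second was largely known. GC content therefore stays open as a part of the cause. Whether most transcripts per cell rose or fell stays open without an added standard. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes (148, highest other 3), and of the 4 splits that part all number pairs 1, again the real one, gave as many with the block (2761, highest other 2), and so few splits cannot give a share under 0.05.

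The second pattern is that basal 3 and induced 3 deviate from their groups together, with a correlation of 0.717 across genes. GC-dependent recovery could produce this, but after each library's trend with the GC content of whole transcripts was removed the correlation was still 0.646. Thus GC content as measured on whole transcripts is not the whole cause. The GC content of the amplified stretches was not used, so recovery that depends on it stays open. Loss of long transcripts would give a negative rank correlation with length within GC groups, and the median over 10 groups was -0.0487. Since reads of amplicon libraries do not scale with transcript length, this value cannot settle the question. A shared preparation, well plate or day may remain as an explanation, and the labels give none to test. No biological explanation was tested.

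The third pattern is the pair of list shifts, higher mitochondrial and lower HIF and glycolysis genes. They were compared with 10000 random lists matched on whole-transcript length, GC content and mean level. The median of the 154 mitochondrial genes (0.19) lay at percentile 100, where the upper end of the central 95% of random medians was 0.07. That of the 40 HIF and glycolysis genes (-0.46) lay at percentile 0, where the lower end was -0.08. These values argue against those properties as the source. Random lists do not keep the correlation between members, so the percentiles are no test of the shifts themselves. With an estimated correlation the respiratory, mitochondrial ribosomal and glycolysis lists had adjusted p = 0.0727 each and the HIF list 0.0929 (camera in limma). Raised PAM is one candidate explanation, and doxycycline itself, an inhibitor of mitochondrial protein synthesis, is another. With 0 libraries that had doxycycline at basal PAM, they cannot be told apart, since every induced library had both. A difference in oxygen or cell density between wells was not tested.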
